A study of Arabidopsis thaliana with 2 samples.

How the data were processed

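The series addresses Argonaute 3 (AGO3), 1 of the 10 Arabidopsis thaliana AGO proteins, which bind small RNAs. Total RNA of siliques, the seed pods, was taken from Col-0 plants carrying the ago3-3 mutation at 1 to 5 days after pollination, depleted of ribosomal RNA and sequenced with a kit that keeps the strand. The labels used here describe 2 libraries, both from ago3-3 plants. The series' design also names wild-type Col-0 siliques, whose libraries were not analysed separately and may be part of the merged set below.

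Per the submitters' processing notes, the tools were CASAVA 1.8, TopHat2 (a spliced aligner) and Cufflinks (a transcript assembler), on genome build TAIR10. The versions of TopHat2 and Cufflinks and their settings are not given in the sources used here. The authors deposited 1 table for the whole series, a merged set of transcript models with the position of each exon. It holds 318041 exon lines in 52608 transcripts at 32758 loci, with 33575 annotated genes named, and a code for how each transcript relates to the annotation. It carries 0 columns with a value per library, and no read count, coverage or expression level. The depth of the libraries is therefore unknown, and which libraries went into the merge is not given in the sources used here. No comparison between genotypes, replicate spread or expression level could be computed, and the tests below compare genes, introns or loci within the merged set. Their p-values and intervals describe counting over those items and not the spread between plants.

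Annotated transcripts are carried over by name into such a merged set whether or not reads covered them. An annotated transcript in the table was therefore not read as a sign of expression. Transcripts with an assembled structure were read as built from reads of at least 1 merged library. Of these, 243 matched an annotated transcript and were counted as annotated. The others fall into new isoforms (at least 1 splice junction shared with an annotated transcript, another structure elsewhere), other exonic overlaps on the same strand, antisense transcripts (overlap with exons of a gene on the opposite strand) and intergenic transcripts (no annotated gene).

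Sequence and gene types came from the TAIR10.1 reference, with a newer gene annotation. The nuclear coordinates of both builds were compared before use. Of 32819 nuclear genes found in both, 32815 overlapped in position and strand, and 99.0% of 127854 annotated nuclear introns in the table were introns of the newer annotation too. Organelle positions were not compared. Tests on introns, intergenic loci and gene types used nuclear chromosomes alone, while genome-wide counts and the background of the gene lists held 145 mitochondrial and 133 chloroplast genes as well. The reference types used here have no separate class for transposable element genes, so genes typed as pseudogene, a type that holds many of them, took their place. This differs from the wording of the plan.

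Gene lists, tests, alternatives and the rule for naming genes were set before the data were examined. For each of 12 lists, the number of members with at least 1 new isoform was set against 10000 random lists of genes with the same annotated exon number (strata of at least 100 genes), with a two-sided permutation p and Benjamini-Hochberg adjustment over the 12 lists. Antisense transcripts were tested likewise with matching on gene length in 10 classes. Pseudogenes were compared with protein-coding genes by shuffling the type within exon number. Intergenic loci were placed at random 1000 times in the sequence between genes of their chromosome. The pericentromere was the run of 500 kb bins with a protein-coding gene density below 0.5 of the chromosome median. Retained introns were compared with the other introns of the same gene by shuffling the retained state within the gene. Splice-site shares were compared by Fisher's exact test, two-sided. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, and a count of 0 is given with the share that 3 of the total would make. The threshold was 0.05.

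Chosen for naming were all AGO genes, up to 4 members per list with the most new isoforms, and the 10 genes with the most. So were the 10 longest multi-exon intergenic loci and antisense transcripts, and the 10 pseudogenes with the most new transcripts. Only some of these list members, loci, antisense transcripts and pseudogenes are described below. Alternatives changed the unit counted, the matching, the classes used, the bin size (250 kb), the distance to a gene (1000 bp), the exon number of loci, the intron length (60 to 2000 nt) and the minimum intron number (5). Alternatives added after the data were examined were a protein-coding background, a background of nuclear genes, the transcribed pseudogene type, sequence without assembly gaps, introns absent from the newer annotation, and placement of distant loci at least 1000 bp from genes. After the data were examined the pericentromere and pseudogene results were also put on the scale of their own random expectation, so that alternatives could be compared.

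The statistics were tested on simulated data. For the list test, run on the exon numbers of 33575 genes, 8 of 200 lists of 20 genes without excess gave p below 0.05, and 195 of 200 with an excess of 40 points did. For the type test on the same genes these numbers were 12 of 200 without a deficit and 200 of 200 with the probability at 0.5 of the rest. For placement of 300 loci they were 2 of 40 without and 39 of 40 with density lowered to 0.5 in a region, and for introns within 800 genes 2 of 40 without and 40 of 40 with lengths 1.2 times as large. For the list test, other list sizes and smaller excesses were not simulated, so its power for them is unknown. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.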

Results

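The data are the transcript models assembled from strand-specific RNA-seq of Arabidopsis siliques collected 1 to 5 days after pollination. The 2 libraries with labels both came from ago3-3 plants (n = 2). The set is merged for the whole series, whose design also names wild type, and carries no value per library. A transcript in it may therefore come from wild type, ago3-3 or both. What follows describes where assembled transcripts departed from the TAIR10 annotation, with no replicate error, and says nothing on how the genotypes differed.

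AGO3, the gene mutated in the ago3-3 plants, was present with its annotated transcript alone. AGO3 (AT1G31290) lies on the plus strand of chromosome 1 at 11188293 to 11192317, with 3 exons and 3585 nt of spliced sequence, and 0 new isoforms were assembled there. Its neighbour AGO2 (AT1G31280, chromosome 1, 11181711 to 11185344) had 2 new isoforms. In 1 of them the donor of a coding intron lay 3 nt upstream (intron 11182195 to 11182403), and in the other the acceptor of that intron lay 3 nt downstream (11182198 to 11182406). Because an annotated transcript is kept with or without reads, the AGO3 entry does not tell whether the gene was transcribed in the mutant. The labels therefore could not be checked on the mutated gene.

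**Figure D1:**
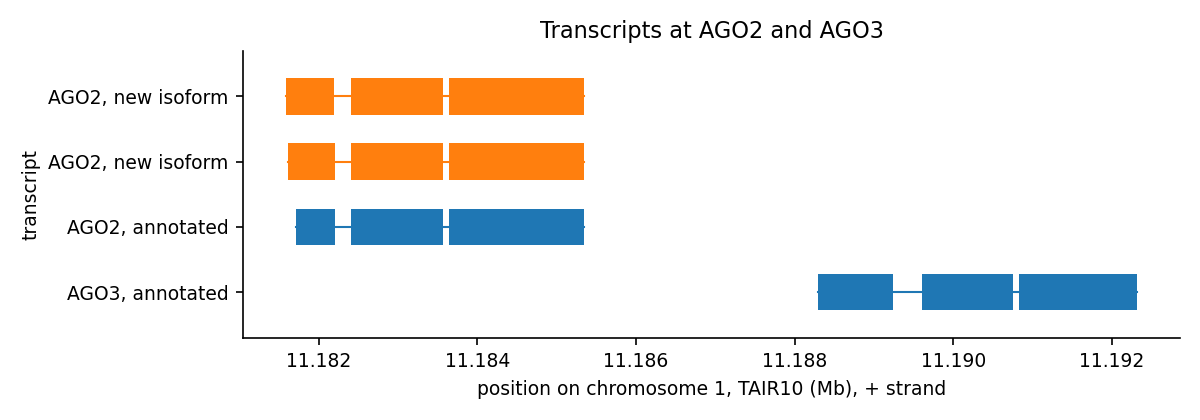
Transcript models at AGO2 and AGO3, with position on chromosome 1 in Mb on the x axis and 1 transcript per line. Boxes are exons and lines are introns, blue for annotated and orange for new isoforms; the 2 new isoforms are at AGO2 and AGO3 has 0.

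Across the AGO family, 6 of 10 genes had a new isoform. AGO1 (AT1G48410, the main carrier of microRNAs) had 2, each reaching from 17884645 to 17892596 on chromosome 1, with 24 exons against at most 23 in its annotated transcripts. Both held introns of AGO1 and of the adjacent gene AT1G48405, and 0 introns absent from the annotation. AGO5, AGO6, AGO9 and AGO10 had 1 each. The acceptor moved 105 nt downstream in AGO5 (AT2G27880, intron at 11875234 to 11875401 on chromosome 2), 27 nt in AGO6 (AT2G32940, 13974794 to 13974897 on chromosome 2) and 18 nt in AGO9 (AT5G21150, 7194713 to 7194795 on chromosome 5), all inside coding sequence. In AGO10 (AT5G43810) annotated sites of the 5' UTR were joined in another pairing (17611362 to 17611844 on chromosome 5), an intron the newer annotation also has. AGO4, AGO7 and AGO8 had 0. The expectation for genes of the same exon number was 4.81 of 10, and the observed 6 was not shown to differ from it (permutation p = 0.636, adjusted p = 1). With 10 genes the interval of the observed share was wide (26.2 to 87.8%).

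New isoforms were found in 13 of 28 genes of small RNA biogenesis and RNA-directed DNA methylation, and in 7 of 13 genes of DNA methylation and demethylation. RDR6 (AT3G49500), the RNA-dependent RNA polymerase of secondary small RNAs, had 3 new isoforms with 5' UTR introns at 18353211 to 18353443, 18353227 to 18353443 and 18353227 to 18353466 on chromosome 3. CLSY1 (AT3G42670), a chromatin remodeller that acts with RNA polymerase IV, had 3, and HST (AT3G05040), an exportin homologue, had 2. CMT2 (AT4G19020), a DNA methyltransferase, had 3 new isoforms, which included retained introns of 127 and 115 nt in the coding region. ROS1 (AT2G36490), a glycosylase that removes methylated cytosine, had 2, with an acceptor 3 nt downstream. Another new intron assigned to ROS1 lay beyond its 3' end (15302624 to 15303060 on chromosome 2). SUVH5 (AT2G35160), a histone methyltransferase, had 2 new isoforms. Matched genes gave 10.9 of 28 (permutation p = 0.503) and 6.43 of 13 (permutation p = 0.975), and neither list passed (adjusted p = 1).

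Among lists for the parts of the silique, new isoforms were present in 7 of 18 seed coat genes, 5 of 15 embryo regulators, 4 of 14 endosperm regulators and 2 of 6 genes of the valve and dehiscence zone. TT16 (AT5G23260), a MADS-box gene of the seed coat, had 3, and STK (AT4G09960), a MADS-box gene of ovule identity, had 2. MINI3 (AT1G55600), a WRKY factor of endosperm growth, had 3, with a coding donor 18 nt upstream and introns upstream of the annotated gene. LEC1 (AT1G21970), a regulator of embryo identity, had 1 intron across the end of its coding sequence (7727283 to 7727763 on chromosome 1), and STM and WOX9 had 1 new isoform each. In the valve list ALC (AT5G67110) had an acceptor 3 nt upstream and RPL (AT5G02030) an acceptor 583 nt upstream. Matched expectations were 4.93, 4.16, 3.28 and 1.69 genes, and none of the 4 lists passed (permutation p from 0.377 to 1, adjusted p = 1). A gene with 1 annotated exon cannot have a new isoform as defined here, which holds for 1 embryo, 4 endosperm and 1 valve gene.

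No seed storage protein or oleosin gene had a new isoform. Of the 12, SESA1 to SESA5 have 1 exon and could not have one, which leaves 0 of 7 and allows a share of up to 42.9%. Nor did any pollen or sperm gene (0 of 5, which allows up to 60%), a list for tissue that was not sampled. Of 9 photosynthesis genes 4 have 1 exon (LHCB1.1, LHCB1.2, LHCB1.3 and PSAD1), and of the other 5 RCA (AT2G39730), the activase of Rubisco, had 1 new isoform, with an intron of 95 nt in its 5' UTR. Expectations were 10.8% of the storage genes, 30.9% of the pollen genes and 11.8% of the photosynthesis genes, with permutation p of 0.463, 0.270 and 1. The photosynthesis count passed from below to above its expectation with length matching (0.0817 genes above) and with every class counted (1.75 genes above). In all 12 lists the matching took no account of expression, for which no value exists here. A gene without reads cannot yield a new isoform, so departures from expectation may follow expression.

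The SR splicing factors, proteins that guide splice-site choice, had new isoforms in 12 of 20 genes against 7.38 in matched genes, which was the smallest p of the 12 lists and did not pass (permutation p = 0.0568, adjusted p = 0.682). SCL33 (AT1G55310) had 3 and RS41 (AT5G52040) had 2. Assembled transcripts also joined SCL33 with the neighbouring gene AT1G55320 (20630065 to 20636892 on chromosome 1). RS31 (AT3G61860), SCL30 (AT3G55460) and SCL30A (AT3G13570) each had an exon absent from the annotation inside a coding intron; these 3 genes were named after their structures were seen. Its donor and acceptor lay 678 nt downstream and 513 nt upstream of the annotated sites in RS31, 923 and 626 nt in SCL30, and 562 and 324 nt in SCL30A. Clock genes had new isoforms in 6 of 13 against 4.15 (permutation p = 0.392, adjusted p = 1). PRR7 (AT5G02810), a clock repressor, had 4, and LHY (AT1G01060), a MYB factor of the clock, kept an intron of 391 nt in its 3' UTR.

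**Figure D2:**
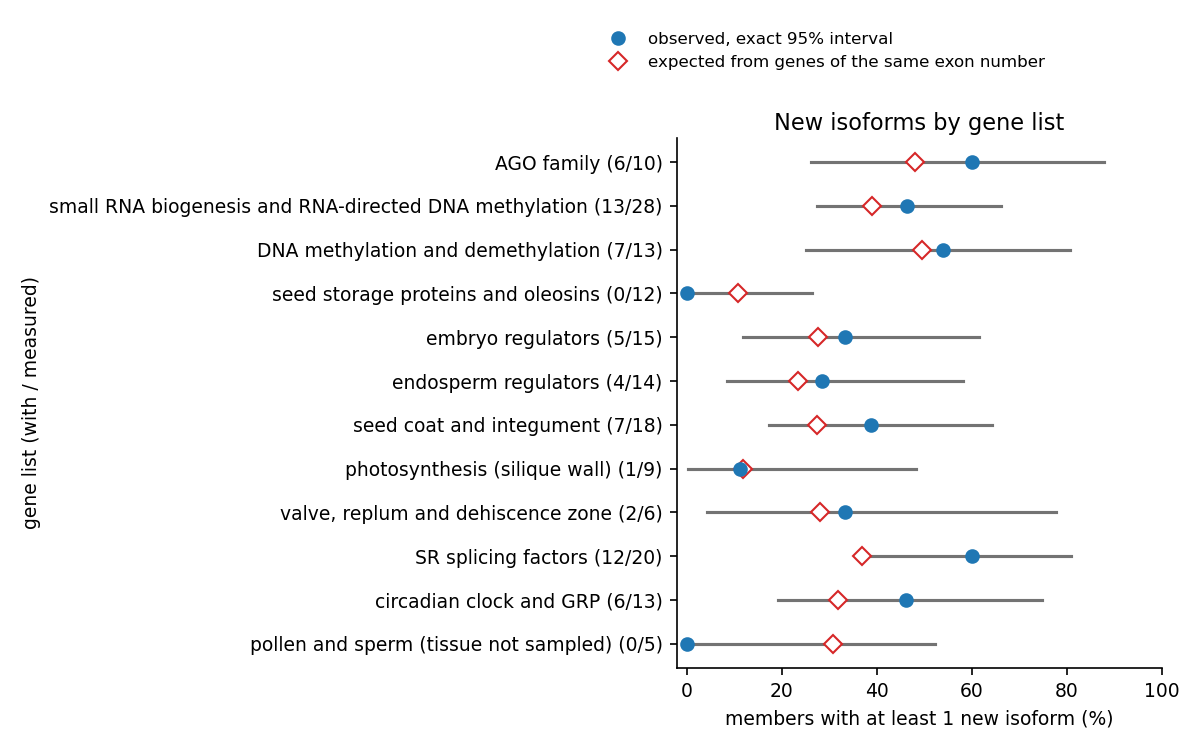
Share of list members with at least 1 new isoform, in percent, for 12 gene lists. Blue points are observed shares with exact 95% intervals and red diamonds the share expected from genes of the same exon number; SR splicing factors lie farthest above theirs in number of genes (12 against 7.38).

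Over the whole genome, 10748 transcripts (20.4%) departed from the annotation. New isoforms made up 9601 transcripts (18.3%, interval 17.9 to 18.6%) at 6365 genes, or 19.0% of annotated genes. The other kinds were 655 exonic overlaps (1.25%, of which 1 is an annotated transcript and not counted among the 10748), 341 intergenic transcripts (0.648%) and 152 antisense transcripts (0.289%). Most genes with a new isoform had exactly 1 (4295), 1363 had 2, and 707 had 3 or more. The share rose with exon number, from 10.7% of genes with 2 exons to 36.7% with 6 to 10 and 63.8% with 21 or more.

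CYCB1;5 (AT1G34460), a B-type cyclin gene at 12595110 to 12599628 on chromosome 1, had the most new isoforms, 13 with 15 new introns. SAR1 (AT1G33410), a nucleoporin gene, followed with 10. AT1G33660, AT1G62920, DUF5 (AT2G47220) and AT3G03350 had 9 each. UPS1 (AT2G03590, a ureide permease), CIPK3 (AT2G26980, a CBL-interacting protein kinase), AT3G18530 and AT4G31570 had 8 each. Many of these isoforms held introns of a neighbouring protein-coding gene as well: 9 of 10 at SAR1, 9 of 9 at DUF5 and at AT3G03350, and 7 of 8 at UPS1, against 0 at the other 6 genes. New structures at AT1G33660 ran past both ends of the gene (12197701 to 12198322 on chromosome 1), with 28 new introns, and some of those at CYCB1;5 lay beyond its 3' end.

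Alternative acceptors were the most frequent change, with 3363 introns (36.5% of 9206 events) in 2763 genes, followed by alternative donors with 1938 (21.1%) in 1677 genes. Introns inside an annotated exon numbered 714 (7.76%), and introns elsewhere with both sites new 1604 (17.4%). Retained introns numbered 1175 (12.8%, in 825 genes) and new pairings of annotated sites 412 (4.48%). Acceptors most often moved 4 nt (221 introns), 3 nt (180) and 5 nt (167) downstream or 3 nt upstream (144). Donors most often moved 4 nt upstream (95), 5 nt upstream (65) or 4 nt downstream (55). Of 8031 new introns, 2054 (25.6%, interval 24.6 to 26.5%) are in the newer annotation. The share was 17.1% for alternative acceptors, 29.0% for introns inside an annotated exon and 43.6% for introns elsewhere with both sites new. Of 9600 nuclear new isoforms, 1720 had neither a new nor a retained intron and combined annotated introns in another way.

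**Figure D3:**
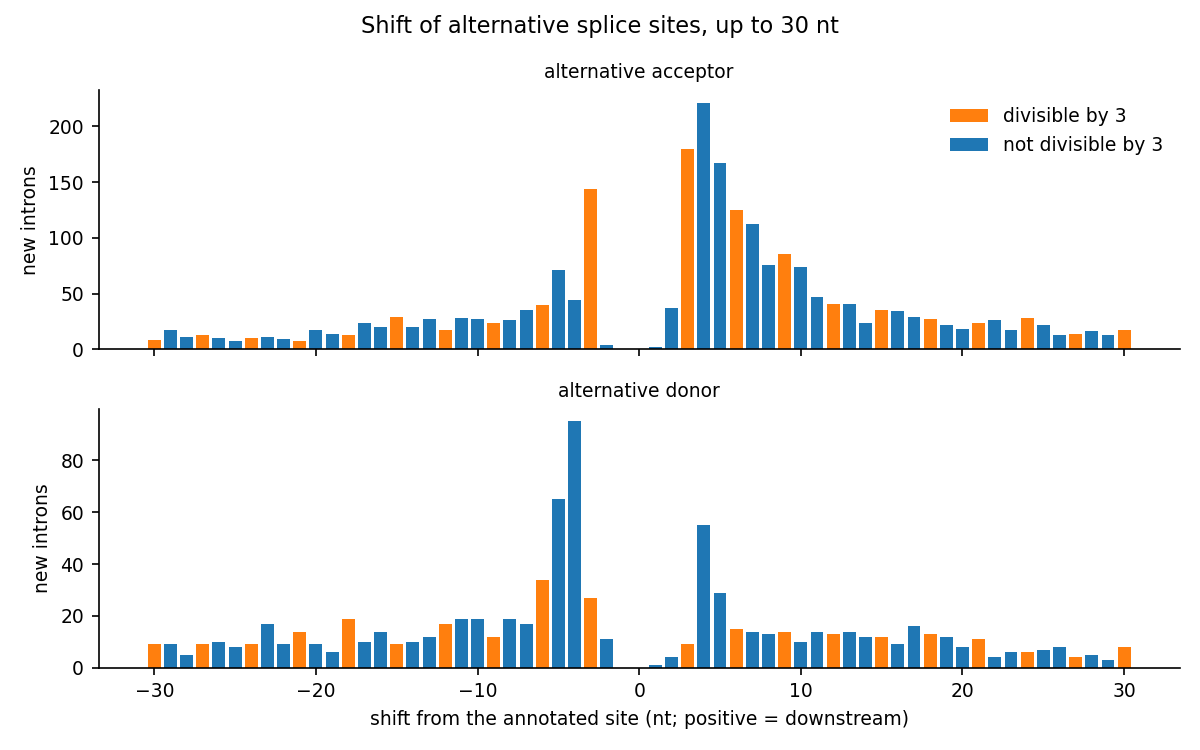
Number of new introns by the shift of the acceptor (top) or donor (bottom) from the annotated site, in nt, up to 30 nt either way, with downstream positive. Orange bars are shifts divisible by 3; the highest bars are 221 introns at 4 nt downstream for acceptors and 95 at 4 nt upstream for donors.

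New introns lay on the 5' side of their gene's coding sequence far more often than annotated introns did. The shares were 20.1% (19.2 to 21.0%) of 7809 and 4.15% of 124262. On the 3' side they were 7.86% and 1.24%, and inside the coding span 67.6% and 94.2% (coding ends taken from the newer annotation). Both sides take in introns beyond the annotated gene, so these are not shares of UTR introns alone. At ROS1 (15308021 to 15314807 on chromosome 2) such an intron lay at 15302624 to 15303060. GT-AG ends made up 95.4% of new and 98.8% of annotated introns (Fisher's exact test, p = 8.98e-90), GC-AG 2.59% and 1.04% (p = 1.96e-28), AT-AC 0.573% and 0.0610% (46 and 78 introns, p = 6.59e-25), and other ends 1.47% and 0.138% (p = 1.04e-65). Introns of 1 gene are not independent, which makes these p-values too small. All 118 new introns with other ends were absent from the newer annotation, among them introns at HST and STK. They include 19 with CT-AC ends, which a GT-AG intron read on the wrong strand would have.

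Retained introns were longer than other introns of the same 820 genes, with a median of 122 nt for 1165 retained introns against 102 nt for 8507 others. The difference of 20 nt lay outside the range of -1 to 6 nt given by shuffling within genes (permutation p = 0.0002, the smallest the draws can give). In genes with at least 5 introns it was 7 nt (109 against 102 nt, permutation p = 0.0026). SUVH5 kept an intron of 459 nt in its 5' UTR, and SCL33 kept 1 of 567 nt in its coding region. Short introns were retained too, such as those of 93 and 96 nt at RS41.

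Between annotated genes 290 nuclear loci were assembled, 99 of them with several exons. The longest spliced one had 5236 nt in 5 exons on the minus strand of chromosome 5 (5040931 to 5047018) and lies in AT5G15537 of the newer annotation. Another on chromosome 5 (8955867 to 8963863, minus strand) had 13 exons and lies in AT5G25755, and a locus on chromosome 4 (6664101 to 6670182, plus strand) had up to 10 exons and lies in AT4G10843. All 3 of those genes are typed protein-coding. Among the 10 longest loci with several exons, 4 lie in long non-coding RNA genes of the newer annotation, with up to 15 exons at 17580275 to 17585600 on chromosome 1 (AT1G07413). Of all 290, 153 (52.8%, 46.8 to 58.6%) lie in a gene on that strand that the newer annotation added, 64 of them long non-coding and 46 protein-coding. Another 12 (4.14%) lie in an annotated gene that the newer annotation extended, among them the locus of 3401 nt at 11453540 to 11457011 on chromosome 1. The share in added genes was 70.7% for loci with several exons and 43.5% for the others (Fisher's exact test, p = 1.24e-05).

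Intergenic loci were thinner around the centromeres than their share of the sequence gives. The pericentromeres held 41 loci, or 4.21 per Mb of intergenic sequence, and the arms 248, or 6.38 per Mb. The ratio was 0.660, against a median of 1.29 (0.981 to 1.64) for random placement, and was 0.512 of that median (permutation p = 0.002, the smallest the draws can give). For loci with several exons it was 0.274 of random. For loci at least 1000 bp from a gene, placed anywhere between genes, the density was higher around the centromeres (2.46 per Mb against 2.11 in the arms, ratio 1.17), which was 0.948 of random and did not pass (permutation p = 0.821). With such loci placed only at least 1000 bp from genes, a setting chosen after that result was seen, it was 0.594 (permutation p = 0.018).

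**Figure D4:**
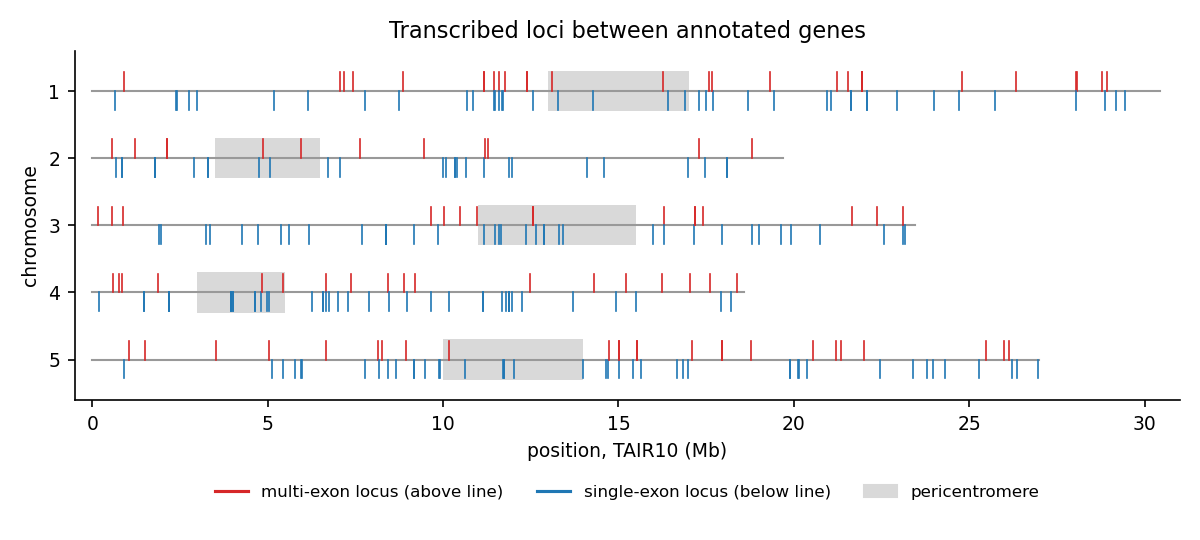
Position of the 290 intergenic loci on chromosomes 1 to 5 in Mb, multi-exon loci in red above the line and single-exon loci in blue below it. Grey marks the pericentromeres, which held 41 of the 289 loci used for placement.

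Genes typed as pseudogene, among them transposable element genes, rarely had new transcripts. Of 3910 such genes 84 had any (2.15%, 1.72 to 2.65%), against 6634 of 26699 protein-coding genes (24.8%). Shuffling the type within exon number gave 284, so the count was 5.12 points below (difference -5.12, permutation p = 0.0002, the smallest the draws can give). Counting new isoforms alone it was 12 against 135 (-3.15 points), and with length matching 84 against 892 (-20.7 points). The larger gap with length matching is built in, since 85.5% of these genes but 20.1% of protein-coding genes have 1 exon and so cannot have a new isoform. For the 926 genes typed transcribed pseudogene, added after the data were examined, 74 had new transcripts against 76.3, and the difference did not pass (-0.251 points, permutation p = 0.824). By their name, transcribed pseudogenes are set apart from the 3910, so the low count among the 3910 may be built in. AT4G07507 on chromosome 4 (4309156 to 4310671) had 7 new transcripts, AT3G42052 on chromosome 3 had 5 and AT3G14800 had 4. AT5G55896 (22628017 to 22633342 on chromosome 5) had 3 new isoforms.

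Antisense transcripts numbered 144 on nuclear chromosomes, opposite 130 genes, of which 98 are protein-coding. The longest of the 52 with several exons had 2878 nt in 3 exons on chromosome 4 (2181107 to 2184156, plus strand) opposite AT4G04408. Only its end overlaps that gene, which lies at 2184059 to 2184400. The newer annotation has AT4G02825 on the transcript's own strand there. BGAL12 (AT4G26140), a beta-galactosidase gene, had an antisense transcript of 6 exons and 1840 nt on chromosome 4 (13243541 to 13245854, plus strand). Of the 126 antisense introns 124 had GT-AG and 2 GC-AG ends on the antisense strand. None had the CT-AC ends of a sense intron read on the wrong strand. The antisense code may leave such transcripts out, so this count is no test of strand errors. Among the new introns of new isoforms 19 had CT-AC ends. The newer annotation holds a gene on the same strand for 60 of the 144 (41.7%, 33.5 to 50.2%). No member of the 12 lists had an antisense transcript. Expectations were at most 0.0776 genes per list, so that test could not have shown a deficit (permutation p = 1 for each list).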

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

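Outside the nuclear chromosomes, which the comparisons of introns and loci used, 25 transcripts beyond the annotation were assembled on the mitochondrial sequence, which has 145 annotated genes, and 0 on the chloroplast sequence, which has 133. The mitochondrial transcripts were set apart because no comparison described them. The count is given as it stands, with no control library to set it against, and no explanation was tested.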

How the results depend on the processing

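The transcribed pseudogene type, the protein-coding and the nuclear background, the sequence without assembly gaps, the introns outside the newer annotation and the restricted placement of distant loci were chosen after the data were examined. No paired analysis was possible, and no replicate was left out, because the merged set carries no value per library and names no library. The unknown depth limits every absence reported.

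For new isoforms over the 12 lists, 58 of 60 results under alternatives kept their direction and side of the threshold. The exceptions were for photosynthesis genes, 0.0817 genes above expectation with length matching and 1.75 with every class counted, from -0.0617, none of which passed. The antisense list test could not change under any setting and says nothing on stability. The pseudogene deficit ended for transcribed pseudogenes (-0.251 points). The deficit may come from the pseudogene type itself, which leaves out those typed as transcribed, and the cause was not tested. The pericentromere deficit ended for loci at least 1000 bp from a gene (0.948 of random). There the loci were restricted and their random positions were not, and with both restricted the ratio was 0.594 of random, a setting chosen with the first result in view.

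Counting loci in place of transcripts gave 98.7% with an annotated match, 19.2% with a new isoform, 1.52% with another overlap, 0.415% antisense and 0.904% intergenic, since a locus can hold several kinds. Multi-exon transcripts alone gave 74.5, 23.6, 1.41, 0.128 and 0.354%. Alternative donors made up 22.5% and retained introns 10.8% with each transcript counted once, and retained introns 11.2% with 1 isoform per gene. The splice-site results kept direction and threshold under their alternatives, as did the retained intron lengths.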

Other observations

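The tests of placement matched on masked sequence or on gene distance, and those on the AT-AC introns split by donor, were chosen after the results they bear on were seen. No explanation by genotype was tested, since the table has no groups.

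Of 10244 nuclear new isoforms and other overlaps, 972 (9.49%) held annotated introns of at least 2 protein-coding genes that do not overlap each other, in 625 different gene sets. The AGO1 isoforms that continue into AT1G48405 are among them, as are most of those at SAR1, DUF5, AT3G03350 and UPS1. This definition replaced a looser one, any overlap with several genes, after its count was seen. A group of tRNA-Pro genes on chromosome 1 had spliced transcripts on the opposite strand, which made up 7 of the 10 longest antisense transcripts with several exons. The longest of these had 6 exons from 10091505 to 10095093 (opposite AT1G28770), and 1 of 8 exons ran from 10096771 to 10102889 (opposite AT1G28820). The newer annotation has the long non-coding RNA genes AT1G06177 and AT1G28715 there.

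Loci between annotated genes might be unannotated ends of neighbouring genes, or might come from reads shared between repeat copies. The values argue against repeat copies as the general source, but not as the source of some loci. The distances to genes cannot decide on gene ends, for the reason given below. Unannotated ends account for some, since 12 of the 290 loci are now part of an extended gene, while 153 lie in an added gene. Repeat copies may account for others. Single-exon loci in the pericentromeres at 3968280 to 3968413 on chromosome 4 and 11726033 to 11728691 on chromosome 5 were 100% and 95.2% masked. Within 500 bp of a gene on the same strand lay 16.6% of loci, against 21.5% (17.3 to 26.3%) for random placement. An end that the assembler joined to its gene is not counted as intergenic, which lowers this share by construction. Within 500 bp of any gene, on either strand, lay 43.3% of loci, against 40.1% (34.6 to 46.0%) for random placement. Most loci nonetheless lay farther from a gene of the same strand. The share of masked bases (lower case in the reference) averaged 25.3% over loci against 37.6% (35.0 to 40.1%) for random placement. The lower density around centromeres could in turn follow from repeat content or from the distance to genes. With random positions matched on masked share within 10 points the observed ratio was still 0.658 of random, and with positions matched on distance to the nearest gene within a factor of 1.5 it was 0.594 for 282 loci, both below the 95% range, so neither alone accounts for all of the deficit. The unknown depth, and the planned setting that ended the call, leave the deficit open.

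AT-AC ends were 9.44 times as frequent, by odds, among new as among annotated introns, and may be introns of the minor (U12) spliceosome or chance sequence matches that the aligner allowed. The donor ATATCC of U12 introns was carried by 16 of the 46 (34.8%, 21.4 to 50.2%), against 66 of 78 annotated ones (84.6%) and 0.225% of AT dinucleotides in annotated introns of chromosome 1. The tables argue against either as the source of all 46. Of the 16 with that donor 12 (75%) are in the newer annotation, above the 25.6% of all new introns, and of the other 30 only 2 (6.67%) are, below it (Fisher's exact test between the parts, p = 3.37e-06). A mixture of both stays open.

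Alternative sites in coding sequence might keep the reading frame more often than those in UTRs, as removal of frame-shifted transcripts might give. No such excess was seen. Shifts divisible by 3 made up 34.8% of 4310 introns inside the coding span and 37.9% of 910 outside it (-3.11 points, Fisher's exact test, p = 0.0792). The sites outside, taken as UTR, include some beyond the gene, as at ROS1 and SAR1. These may be coding in a neighbouring gene, so the contrast cannot decide the question. Without shifts of 3 nt the difference was -4.18 points (Fisher's exact test, p = 0.0177). For shifts up to 30 nt it was -7.97 points (Fisher's exact test, p = 0.00316). Both go the other way and share this limit. The weight given to these subsets was decided after the main value was seen. Whether tandem sites 3 nt apart alone make such an excess cannot be told apart, because there was no excess to explain.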
